A study of Homo sapiens with 31 samples.

How the data were processed

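Single-cell RNA was measured in 31 libraries from ileal lamina propria (11 involved and 11 uninvolved) and blood (9). Per the labels, biopsies were taken along surgical resections, the epithelium was stripped with EDTA, the tissue was digested with collagenase and DNase, red cells were lysed and dead cells depleted, and libraries were made with 10x V1 (3 libraries) or V2 (28 libraries) chemistry. The same preparation text stands beside the blood libraries. Per the submitters' notes, the authors made the deposited matrices of UMI counts with Cell Ranger 2.0 on GRCh38. They did not state the annotation release. The deposited files hold raw counts for every possible barcode (737280 per library) and 33694 genes, with no cell filter and no normalization, and 0 columns belonged to no sample. Genes are named by the symbols and Ensembl identifiers of these files.

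The total counts per library ranged from 2044519 to 43741943 UMIs (median 15498922). Intervals and floors given for single genes cover counting error only. A check for libraries copied from each other found 0 identical pairs.

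Choices in this section were made before the data were examined unless said otherwise. Barcodes were kept as cells with 800 to 25000 UMIs and at most 25% mitochondrial UMIs. Doublets were scored per library by the Scrublet method, and the highest-scoring cells were removed in the number expected from 0.8% per 1000 cells, 5852 in all. The mitochondrial limit removed 3687 barcodes of involved ileum, 9452 of uninvolved ileum and 13 of blood. Free (ambient) RNA was profiled per library from barcodes with 10 to 100 UMIs.

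All 124824 cells, doublets included, were clustered together in scanpy 1.11.5 and igraph 0.11.9 under Python 3.11.15, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Counts were scaled to 10000 per cell and logged, 2000 variable genes seen in at least 50 cells and 30 principal components were used, and a graph of 15 exact nearest neighbours was partitioned by the Leiden method at resolution 1. Immunoglobulin and T cell receptor genes, mitochondrial, ribosomal and haemoglobin genes, immediate early and heat shock genes and sex chromosome-linked expression markers were kept out of the features. Of 98 clusters 45 had at least 50 cells. A cluster took the class whose fixed markers averaged highest against the mean of all clusters, with at least 3 of them detected in 5% of its cells and raised by a log2 fold of 0.5. A cluster whose 10 leading genes held more markers of another class than of its own was set aside under its number, and classes carry the suffix "like" because they rest on RNA alone. These naming thresholds, the number of variable genes, components and neighbours and the Leiden resolution were set while the clusters were being made. Clusters in which over 50% of cells were scored as doublets were set aside (0.124% of involved, 0.107% of uninvolved and 0.143% of blood cells), as were small clusters (0.044%, 0.040% and 0.049%). Cluster 5 (0.337%, 0.176% and 19.3%), cluster 13 (3.72%, 2.75% and 0.063%) and cluster 44, led by the enteroendocrine genes PYY and GCG (0.016%, 0.109% and 0%), were set aside by that rule. Epithelial-like cells made up 3.42%, 7.77% and 0%, erythroid-like cells 0.064%, 0.020% and 1.343%, and platelet-like cells 0%, 0% and 2.106% of all cells in that order.

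Class shares are percents of a library's cells without epithelial-, erythroid- and platelet-like cells. Involved and uninvolved ileum were compared by a two-sided permutation test with 100000 resamples, whose smallest possible p is 1e-05, and blood and uninvolved ileum by a two-sided exact permutation test, with Benjamini-Hochberg adjustment over the classes. A plasma-like cell was given the heavy chain class with the most UMIs if it had at least 10 heavy chain UMIs and 60% of them in that class, which held for 15684 of 15838 ileal plasma-like cells (99.03%).

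For gene tests, counts were summed per library and class, with at least 20 cells per library and 5 libraries per group. Sums were normalized by TMM, filtered with filterByExpr and tested by quasi-likelihood in edgeR 4.0.16 under R 4.3.3, with Benjamini-Hochberg adjusted p below 0.05 called. Mast-like cells reached 20 cells in 3 involved and 4 uninvolved libraries and were not tested. Gene values are log2 fold changes with their SE, and means use a prior count of 2. Sex chromosome-linked markers and variable, diversity and joining segments of antigen receptors were left out. Gene lists, 37 in number and written before the data were examined, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and classes of a comparison. They were tested again with an estimated correlation and with fry. Members were also counted over all genes tested and adjusted over the list alone. DESeq2 1.42.0 was run as a second tool.

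Named genes follow a rule fixed in advance. In each class these are the 12 passing list members with the largest absolute fold change, then, among passing genes with a mean of at least 5 on the log2 CPM scale, the 6 largest rises and 6 largest falls. Clone names, immunoglobulin genes outside B-like and plasma-like cells and genes of whose counts free RNA could supply over 50% are left out of the last 2 groups. Therapy targets are given as a count with the passing ones named, and a list member may be given where its list is described. Where a gene had 0 counts in a group the fold is a bound against 3 counts over the group, and with 1 to 3 counts a ratio with its 95% counting interval is given.

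Cell states were correlated across involved libraries with at least 20 cells of both classes (at least 6 libraries) by Pearson r and Spearman rho, with permutation p and adjustment over 21 pairs. The series calls the resections paired, but the labels name no patient for an ileal library, so each test treats libraries as unpaired.

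The tests were tried on simulated counts with planted changes, to which the rates below apply. Planted 2-fold changes were called for 89% of genes in T-like, 91% in NK/ILC-like, 85% in B-like, 82% in plasma-like, 70% in MNP-like, 57% in endothelial-like, 37% in fibroblast-like and 12% in pericyte and smooth muscle-like cells. In blood comparisons 93% (T-like), 93% (B-like) and 95% (MNP-like) were called. For 4-fold changes 88% were called in pericyte and smooth muscle-like cells and 100% in the other classes.

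Alternatives written before the data were examined were RLE scaling, DESeq2, no filter other than a count above 0, ambient counts subtracted, at least 50 cells per library, at least 1500 UMIs per cell, at most 10% mitochondrial UMIs, doublets kept, Leiden resolution 2 (117 clusters), chemistry as a covariate, V2 libraries alone, all cells in the denominator, log2 percents, stricter and summed isotype calls, and each library left out in turn. Added after seeing the data were fits without replicate 2 of each ileal group (rich in epithelial-like cells), T-like cells with clusters 5 and 13, MNP-like cells without cluster 22, plasma-like cells without clusters 9 and 33, fibroblast-like cells without cluster 30, and clusters from another random seed. Figures were drawn with matplotlib 3.10.9.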

Results

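The series holds single-cell RNA profiles, made on the 10x platform, of lamina propria from surgical ileal resections of people with Crohn's disease and of their blood. Of 31 libraries 11 came from involved (inflamed) ileum, 11 from uninvolved ileum and 9 from blood. Total UMIs per library ranged from 4702504 to 29216183 in involved ileum, from 7547435 to 27610114 in uninvolved ileum and from 2044519 to 43741943 in blood. After quality filters 118972 cells remained, 43630 from involved ileum, 40350 from uninvolved ileum and 34992 from blood. The median over libraries of the median UMIs per cell was 1929, 2204 and 2827 in that order. Each group held 1 V1 library and the others were V2. The labels do not name the donors of the ileal libraries, so the p-values measure the spread between samples and not between people.

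The first comparison asks which lamina propria cell classes differ in abundance between involved and uninvolved ileum. T-like and plasma-like cells together made up most of the lamina propria cells in both. The mean T-like share was 39.8% ± 15.5 (SD, n = 11) in involved and 52.1% ± 16.1 (n = 11) in uninvolved ileum. MNP-like cells (monocytes, macrophages and conventional dendritic cells) made up 8.64% ± 5.98 against 5.23% ± 2.17, and B-like cells 15.2% ± 12.3 against 8.90% ± 10.4. Plasmacytoid dendritic cells, which make type I interferon, made up 0.368% ± 0.562 against 0.0547% ± 0.116. Glia-like cells made up 0.0805% ± 0.197 against 0.536% ± 0.649.

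None of these share differences passed the two-sided permutation test after Benjamini-Hochberg adjustment over the classes, and 2 had an unadjusted p below 0.05. These were plasmacytoid dendritic cells (p = 0.0457, adjusted p = 0.290, 8 of 11 involved libraries above the uninvolved median, difference within V2 0.334 points) and glia-like cells (p = 0.0160, adjusted p = 0.224, 1 of 11 above, within V2 -0.450 points). For T-like cells p was 0.0829 (adjusted p = 0.290, 2 of 11 above, within V2 -14.9 points), and for MNP-like cells 0.0761 (adjusted p = 0.290, 8 of 11 above, within V2 3.34 points). NK/ILC-like cells were at 3.16% ± 1.66 against 4.65% ± 2.94 (adjusted p = 0.439) and fibroblast-like cells at 2.59% ± 3.5 against 1.33% ± 1.59 (adjusted p = 0.608), a difference of 0.140 points within V2. Plasma-like cells were at 21.98% ± 9.94 against 20% ± 21.6, a difference of 8.01 points within V2, and endothelial-like cells at 2.08% ± 2.55 against 1.72% ± 1.59, and adjusted p was 0.439 or more for both and for the remaining classes. Involved T-like cells came mainly from clusters 0 (32.3%) and 6 (26.6%) and uninvolved ones from clusters 0 (49.0%) and 3 (32.3%). Lymphocyte clusters 5 (led by GNLY and NKG7) and 13 (IFNG and GZMK), set aside for markers of another class, were counted in the denominator. Cluster 13 held 3.72% of involved, 2.75% of uninvolved and 0.063% of blood cells.

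**Figure D1:**
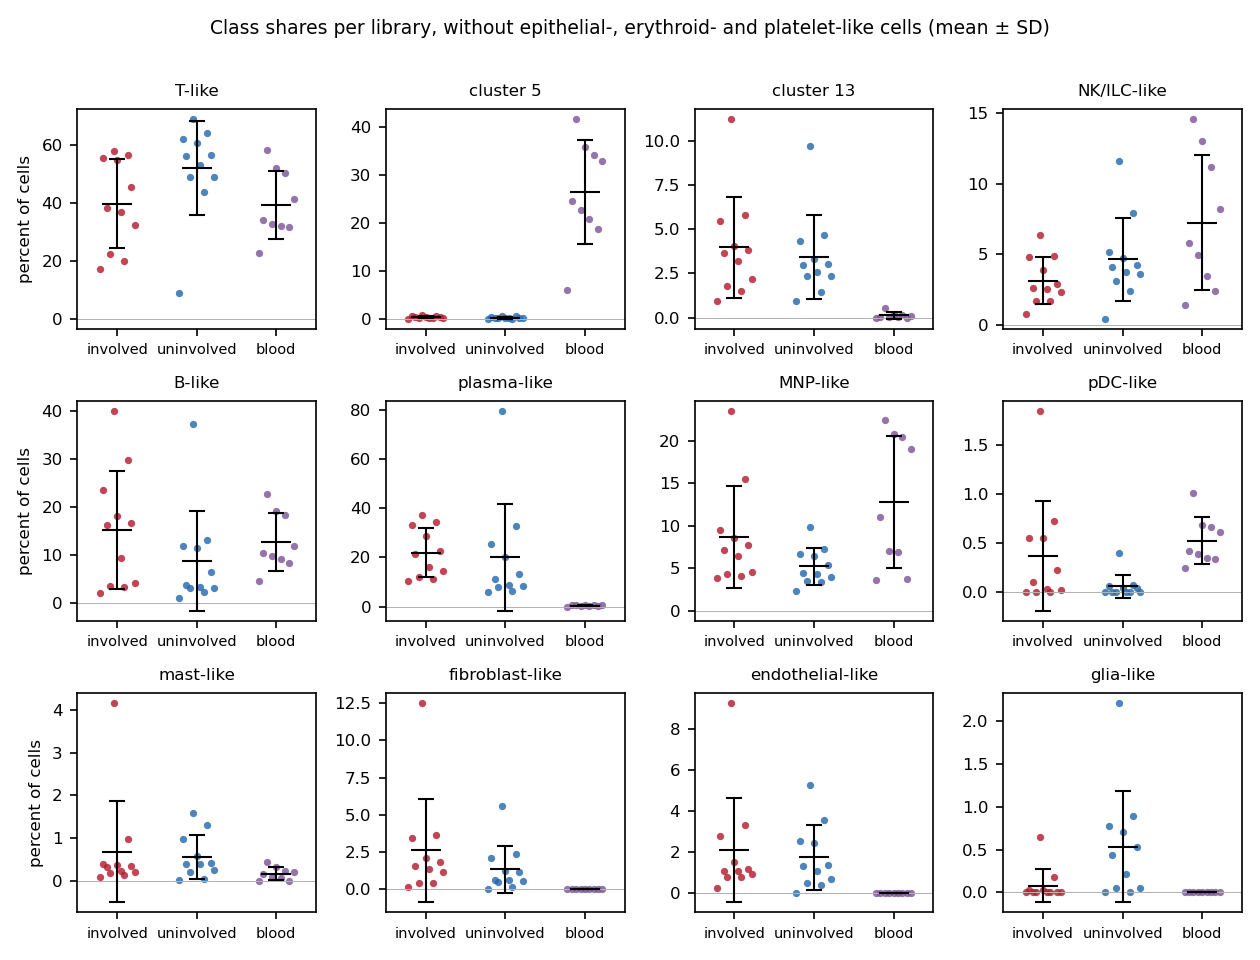
Percent of cells, without epithelial-, erythroid- and platelet-like cells, in 12 classes (y axes, each panel on its own scale), per library (points) with the group mean and SD, for involved ileum, uninvolved ileum and blood. T-like cells average 39.8% in involved and 52.1% in uninvolved ileum, and the libraries of both groups overlap.

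Plasma-like cells of involved ileum carried more IgG and less IgA. IgG cells, which in healthy gut are few beside IgA cells, averaged 31.5% ± 29.3 (SD, n = 11) of the plasma-like cells called by heavy chain in involved ileum and 8.93% ± 4.70 (n = 11) in uninvolved ileum. IgA cells averaged 59.5% ± 27.7 against 79.3% ± 7.46, and IgM cells 9.01% ± 4.0 against 11.8% ± 4.76. The involved libraries spread widely, with IgG from 2.76% to 82.0% (median 19.0%), against 2.16% to 19.5% (median 8.16%) in uninvolved ileum. The IgG difference of 22.5 points gave a permutation p of 0.0191, with 8 of 11 involved libraries above the uninvolved median, and the IgA difference of -19.7 points gave p = 0.0379, with 3 of 11 above. The IgM difference of -2.79 points did not pass (p = 0.153, 3 of 11 above, within V2 -3.03 points, p = 0.135). Within V2 libraries the IgG difference was 16.8 points (p = 0.0571) and the IgA difference -13.8 points (p = 0.113), so neither passed there, and V1 has 1 library per group, which gives no value. The IgA call was also lost on leaving out involved replicate 1 (-15.0, p = 0.0692), 3 (-17.3, p = 0.0660), 4 (-16.1, p = 0.0674) or 7 (-17.4, p = 0.0668), or uninvolved replicate 1 (-18.5, p = 0.0585) or 5 (-19.3, p = 0.0505).

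**Figure D2:**
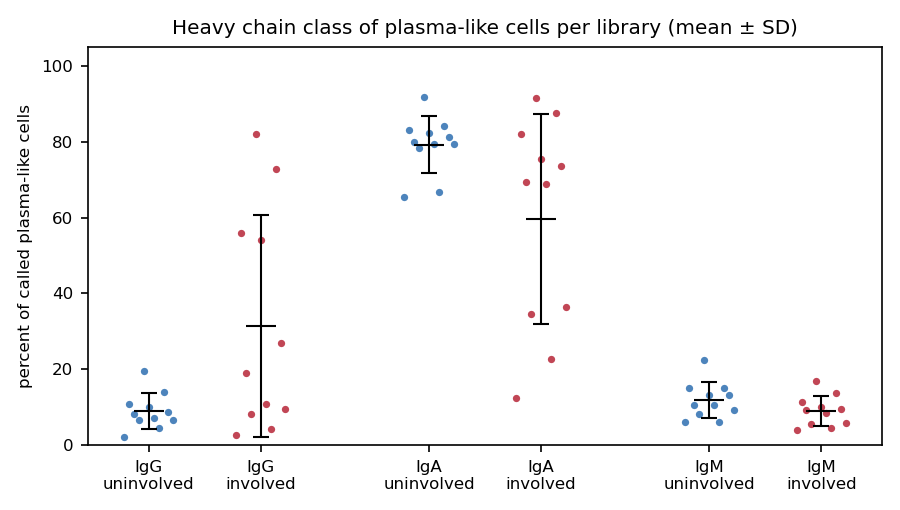
Percent of heavy-chain-called plasma-like cells that are IgG, IgA or IgM (y axis), per library (points) with the group mean and SD, in involved and uninvolved ileum. IgG ranges from 2.76% to 82.0% in involved libraries and from 2.16% to 19.5% in uninvolved ones.

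Within plasma-like cells 3 of 4 IgG heavy chain genes rose when adjusted over the list alone and 0 passed over all genes. The interferon gamma and NF-kB lists had positive medians, and the IgA, IgM and joining chain list had a negative one. The 3 IgG genes were IGHG1, which rose by 2.82 ± 0.83 (log2, SE, 8 of 11 involved libraries above the uninvolved median), IGHG3 by 2.62 ± 0.87 (9 of 11) and IGHG2 by 2.35 ± 0.76 (7 of 11). IgG subclass genes are close in sequence, so the assignment of UMIs among them is uncertain. In the IgA, IgM and joining chain list JCHAIN, the chain that links antibody polymers, was at -0.56 ± 0.36 and IGHA1 at -0.38 ± 0.23, and 0 of 4 members passed alone. Of the 12 interferon gamma genes 4 rose over the list alone, each in 9 of 11 libraries. APOL6 rose by 0.98 ± 0.34, TAP1, the peptide transporter for class I presentation, by 0.67 ± 0.25, WARS by 0.53 ± 0.20 and the transcription factor IRF1 by 0.48 ± 0.19. Of 15 NF-kB and TNF response genes 3 rose over the list alone: TNFAIP2 by 1.30 ± 0.39 (10 of 11), IER3 by 1.24 ± 0.34 (10 of 11) and SOD2, the mitochondrial superoxide dismutase, by 0.89 ± 0.30 (9 of 11).

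By camera with a preset correlation the lists of IgG heavy chains (median 2.49, adjusted p = 0.00496), interferon gamma (0.51, adjusted p = 1.77e-05), NF-kB (0.29, adjusted p = 0.00225) and type I interferon (0.42, adjusted p = 0.0218) were called up in plasma-like cells. None of the 10 list calls in this class held with an estimated correlation (adjusted p from 0.353 to 0.550). Also called up were the lists of endoplasmic reticulum stress and secretion (0.09, adjusted p = 0.0305), glycolysis (0.18, adjusted p = 0.0358) and oxidative phosphorylation (0.21, adjusted p = 0.0230). The IgA, IgM and joining chain list (median -0.25, adjusted p = 0.0459) and the stress list (-0.03, adjusted p = 0.00420) were called down. The epithelial marker list was called down too (adjusted p = 0.00246), with a median of 0.01 and a mean of -0.19. Within V2 libraries the calls of the IgG (adjusted p = 0.0659), IgA, IgM and joining chain (0.158) and glycolysis (0.151) lists were lost. With ambient counts subtracted those of type I interferon (0.0929), NF-kB (0.122), IgA, IgM and joining chain (0.0628), secretion (0.0592) and glycolysis (0.302) were lost, and without clusters 9 and 33, added after seeing the data, those of NF-kB (0.0719), IgA, IgM and joining chain (0.0830) and glycolysis (0.185). By edgeR 0 of 7054 genes passed over all genes, 491 had an unadjusted p below 0.05 and DESeq2 called 18, and leaving out involved replicate 11 gave 4. Of the plasma-like cells 81.6% came from cluster 2 in involved ileum and 54.1% from cluster 9 in uninvolved ileum, where uninvolved replicate 1 held 90.9% of cluster 9.

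In T-like cells of involved ileum most regulatory T cell genes were higher, and some genes of tissue residency and immediate early response lower, when each list was adjusted alone. CD69 (ENSG00000110848), an early activation antigen that also keeps T cells in tissue, fell by -1.36 ± 0.24 (log2, SE, adjusted p = 0.0332, 0 of 11 involved libraries above the uninvolved median). The stress list fell here too, and whether digestion or cluster shifts lowered residency genes was not tested. Of 12 regulatory T cell genes 10 rose over the list alone and 0 passed over all genes. They included TNFRSF18 by 1.68 ± 0.44 (9 of 11), LAYN by 1.55 ± 0.36 (11 of 11), FOXP3, the lineage factor, by 1.40 ± 0.36 (10 of 11) and IKZF2 by 1.30 ± 0.28 (11 of 11). CTLA4, the inhibitory receptor, rose by 0.82 ± 0.29 (10 of 11) and TIGIT by 0.61 ± 0.27 (9 of 11), both over the list alone.

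Of 10 residency genes 1 fell over all genes (CD69) and 4 over the list alone. Among them were CCR9, the small bowel homing receptor, by -1.17 ± 0.44 (3 of 11 above), RGS1 by -0.76 ± 0.21 (0 of 11) and JAML by -0.53 ± 0.20 (1 of 11). The follicular helper and activated T cell list was mixed, with 5 rises and 2 falls over the list alone. CXCL13, the chemokine that draws B cells into follicles, rose by 3.76 ± 1.07 (8 of 11), TOX2 by 1.06 ± 0.38 (10 of 11) and TNFRSF9 by 0.93 ± 0.30 (10 of 11). CD40LG fell by -0.74 ± 0.19 (1 of 11 above) and ICOS by -0.57 ± 0.22 (2 of 11). In the cytotoxic list GNLY rose by 3.43 ± 0.84 (9 of 11) and GZMB by 2.16 ± 0.62 (7 of 11) and CCL5 fell by -1.27 ± 0.34 (1 of 11) over the list alone. The list as a whole was not called (median -0.21, mean 0.06, adjusted p = 0.135). Of 18 immediate early and dissociation stress genes 6 fell over the list alone, with EGR1 at -1.17 ± 0.41, FOS at -1.10 ± 0.32 and JUN at -0.83 ± 0.22 (JUN 0 of 11 above). GBP5, an interferon gamma target, rose by 0.67 ± 0.19 (11 of 11) over its list alone. Markers of other cells moved with these groups: IGHG2 rose by 3.76 ± 0.83 and the epithelial gene FABP1 fell by -3.15 ± 0.93 (2 of 11 above) over their lists alone.

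The camera calls in T-like cells were regulatory (median 0.99, adjusted p = 6.44e-10), follicular helper and activated (0.46, adjusted p = 0.00314), interferon gamma (0.20, adjusted p = 0.0152) and metallothionein (0.90, adjusted p = 0.0142) up. With an estimated correlation none of the 8 calls in this class held (adjusted p = 0.208 for regulatory and residency, up to 0.410 for metallothionein), and within V2 the metallothionein call was lost (adjusted p = 0.0786). Stress (-0.51, adjusted p = 2.59e-08) and residency (-0.65, adjusted p = 1.3e-06) were called down. The marker lists of immunoglobulin (0.37, up, adjusted p = 1.83e-06) and epithelium (-0.51, down, adjusted p = 3.67e-05) were also called. Ambient subtraction was scaled to T-like immunoglobulin, so the former lost its call by construction (adjusted p = 0.460). By edgeR 5 of 8533 genes passed over all genes, 3 up and 2 down, and by DESeq2 70. The others were chosen after their values were seen. PVRL3 was at -1.27 ± 0.24 (adjusted p = 0.0332, 0 of 11 above). Higher were KIAA0319L (1.06 ± 0.21, adjusted p = 0.0489, 11 of 11), AC002331.1 (3.04 ± 0.55, adjusted p = 0.0332, 10 of 11) and CTD-2020K17.1 (0.94 ± 0.19, adjusted p = 0.0489, 11 of 11). Within V2 libraries CD69 was at -1.32 (adjusted p = 0.0686), and it lost its call in 6 of 22 fits without 1 library (involved replicates 1, 3 and 10 and uninvolved replicates 3, 5 and 7, log2 fold changes over all 22 from -1.48 to -1.26). The count was 0 with at least 1500 UMIs per cell. Without the involved replicate in brackets it was 0 (1, 3, 10), 1 (4), 3 (7), 9 (8), 14 (2), 19 (5) and 67 (11). Without the uninvolved one it was 1 (3, 5, 7), 2 (9), 3 (8) and 11 (10).

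MNP-like cells of involved ileum carried higher levels of inflammatory monocyte and activated dendritic cell genes. Of 20 inflammatory genes 16 rose when adjusted over the list alone, and 0 passed over all genes. S100A8, a calcium-binding alarmin of monocytes and neutrophils, rose by 2.37 ± 0.71 (log2, SE, 10 of 11 involved libraries above the uninvolved median), and its partner S100A9 by 1.85 ± 0.61 (10 of 11). The neutrophil-attracting chemokines rose too, CXCL1 by 2.26 ± 0.79 (7 of 11), CXCL3 by 2.15 ± 0.64 (9 of 11) and CXCL8 by 1.13 ± 0.46 (10 of 11). The cytokines TNF and IL1B rose by 1.91 ± 0.61 (8 of 11) and 1.43 ± 0.41 (9 of 11). Of 14 activated dendritic cell genes 13 rose over the list alone. Among them the chemokine CCL19 rose by 3.93 ± 1.19 (7 of 11) and its receptor CCR7 by 2.84 ± 0.92 (9 of 11). LAMP3 rose by 2.58 ± 0.79 (7 of 11), TXN by 2.45 ± 0.61 (11 of 11) and the maturation marker CD83 by 1.18 ± 0.35 (10 of 11).

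Of 15 NF-kB and TNF response genes 12 rose in MNP-like cells over the list alone, including ICAM1 by 1.44 ± 0.36 (9 of 11), NFKB1 by 1.43 ± 0.39 (10 of 11) and the inhibitor NFKBIA by 1.40 ± 0.38 (9 of 11). Interferon gamma genes rose in 4 of 15 cases over the list alone, with IDO1 by 1.93 ± 0.61 (7 of 11) and IRF1 by 1.48 ± 0.39 (10 of 11), and LDHA of the glycolysis list by 0.87 ± 0.23 (10 of 11). All 4 metallothioneins tested rose over the list alone, led by MT1G (3.23 ± 1.12, 8 of 11), although MT1 genes are close in sequence and their counts uncertain. Resident macrophage genes had a median of -0.45, and 0 of 19 passed over the list alone. The scavenger receptor gene STAB1 was at -0.82 ± 0.33 (2 of 11 above), C1QA at -0.51 ± 0.21 (3 of 11) and APOE, in the other direction, at 3.08 ± 0.99 (7 of 11). In the conventional dendritic cell list (median -0.29) CD1E was at -1.20 ± 0.38 (0 of 11), and MHC class II genes had a median of -0.30, with CD74 at -0.35 ± 0.14 (2 of 11).

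Camera called the inflammatory (median 1.38, adjusted p = 8.27e-11), activated dendritic cell (2.05, adjusted p = 1.36e-06) and NF-kB (1.40, adjusted p = 4.05e-09) lists up in MNP-like cells. None of the 10 list calls in this class held with an estimated correlation (adjusted p from 0.353 to 0.410). The interferon gamma (0.99, adjusted p = 3.67e-05), glycolysis (0.46, adjusted p = 0.000331) and metallothionein (2.04, adjusted p = 0.0230) lists were called up too. The resident macrophage (adjusted p = 1.62e-05), MHC class II (adjusted p = 0.00107), conventional dendritic cell (adjusted p = 0.0284) and epithelial marker (median -0.62, adjusted p = 0.00420) lists were called down. By edgeR 0 of 5220 genes passed over all genes, 745 had an unadjusted p below 0.05 and DESeq2 called 136. Leaving out involved replicate 11 gave 82 by edgeR, and leaving out involved replicate 5 or 8 gave 8 each. Cluster 22, led by IL1B, SPP1 and CXCL8, held 29.5% of the involved MNP-like cells, beside 48.9% in cluster 11, which held 87.2% of the uninvolved ones. Without cluster 22, a setting added after seeing the data, the conventional dendritic cell (adjusted p = 0.724), MHC class II (0.137) and metallothionein (0.282) calls were lost, and within V2 that of conventional dendritic cells (0.383).

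In fibroblast-like cells of involved ileum 91 genes rose and 21 fell, with 5 of 9 glycolysis and hypoxia genes, 4 of 8 activated fibroblast genes and 2 of 19 matrix genes among the rises and 1 of 13 homeostatic fibroblast genes among the falls. The chemokine CXCL2 (ENSG00000081041) rose by 3.78 ± 1.02 (log2, SE, adjusted p = 0.0400, 6 of 8 involved libraries above the uninvolved median), and IER3 (ENSG00000137331) by 3.71 ± 0.87 (adjusted p = 0.0326, 6 of 8). S100A4 (ENSG00000196154), a calcium-binding protein of motile mesenchymal cells, rose by 3.38 ± 0.60 (adjusted p = 0.0246, 7 of 8). SOD2 rose by 3.02 ± 0.62 (adjusted p = 0.0283, 7 of 8), the hyaluronan-binding protein TNFAIP6 by 2.62 ± 0.70 (adjusted p = 0.0399, 7 of 8) and the surface marker THY1 by 2.05 ± 0.49 (adjusted p = 0.0326, 7 of 8). The type I collagen chain COL1A1 rose by 2.23 ± 0.57 (adjusted p = 0.0373, 7 of 8) and MT2A by 2.43 ± 0.66 (adjusted p = 0.0400, 6 of 8). The glycolytic enzymes PKM, ENO1 and LDHA rose by 2.83 ± 0.54 (adjusted p = 0.0246, 7 of 8), 2.17 ± 0.50 (adjusted p = 0.0326, 7 of 8) and 1.99 ± 0.45 (adjusted p = 0.0326, 8 of 8). Among the 6 named falls, each with 0 of 8 libraries above the median, the fatty acid-binding protein FABP5 changed by -2.54 ± 0.65 (adjusted p = 0.0373), CCDC102B by -2.30 ± 0.62 and the lipid transporter gene ABCA6 by -2.28 ± 0.62 (both adjusted p = 0.0400). GPX3, the secreted glutathione peroxidase, changed by -2.11 ± 0.55 (adjusted p = 0.0392), NDRG2 by -1.88 ± 0.51 (adjusted p = 0.0399) and ARRDC3 by -1.76 ± 0.51 (adjusted p = 0.0475).

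By list, 5 of 9 glycolysis and hypoxia genes rose in fibroblast-like cells over all genes and 7 adjusted over the list alone (median 1.65, adjusted p = 0.000279, and adjusted p = 0.353 with an estimated correlation). GAPDH rose by 1.82 ± 0.39 (6 of 8) and HIF1A, the hypoxia factor, by 1.30 ± 0.39 (5 of 8) over the list alone. Of 13 homeostatic fibroblast genes 1 (FABP5) fell over all genes and 1 over the list alone, with the protease gene ADAMDEC1 at -2.10 ± 0.96 and CFD at -1.66 ± 0.66 (1 of 8 above for both, list median -1.66, adjusted p = 1.3e-06, and adjusted p = 0.353 with an estimated correlation). The activated fibroblast list had 4 of 8 rises over all genes and 4 over the list alone, TIMP1 by 1.49 ± 0.43 (7 of 8) among them, and camera did not call it (median 1.19, adjusted p = 0.0601). Of 19 matrix genes 2 rose over all genes and 3 over the list alone (COL1A1, COL6A1 by 0.89 ± 0.25, COL1A2 by 0.98 ± 0.29), and the list was not called (median 0.46, adjusted p = 0.141). In the stress list HSPB1 rose by 1.69 ± 0.47 (7 of 8) over all genes and 4 members rose over the list alone, without a call (median 0.33, adjusted p = 0.215). Immunoglobulin transcripts moved with this class: IGLC2 was higher by 2.97 ± 0.72 (adjusted p = 0.0335, 8 of 8), free RNA could account for 23.8% of it, and with doublets kept it turned to -1.87 (adjusted p = 0.307). The immunoglobulin list was called up (median 1.02, adjusted p = 0.0218, and adjusted p = 0.353 with an estimated correlation).

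In all, 112 of 1613 genes passed in fibroblast-like cells, 91 up and 21 down, in 8 against 7 libraries. Within V2 libraries 7 passed, and of the 18 named genes S100A4 (3.53, adjusted p = 0.010) and PKM (2.75, adjusted p = 0.0402) kept their calls, while the other 16 kept their direction with adjusted p from 0.0501 to 0.0708. Chemistry as a covariate gave 16, and requiring 1500 UMIs per cell gave 0. Clusters from another random seed, added after seeing the data, placed other cells in the class (9 against 8 libraries) and gave 63 genes, 47 of them shared. Without the uninvolved replicate in brackets the count was 0 (3, 8), 1 (9), 4 (11), 5 (7), 18 (5) and 20 (6). Without the involved one it was 0 (3, 4, 6), 7 (1, the V2 fit), 17 (7), 227 (8) and 352 (11). Cluster 30 held 63.3% of the involved fibroblast-like cells, 72.5% of it from 1 library, and cluster 23 held 99.4% of the uninvolved ones. Involved replicate 1 gave 45.7% of the involved cells of this class. It was the only V1 library in the full fit, so chemistry was confounded with involvement there.

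In pericyte and smooth muscle-like cells, which wrap small vessels, no matrix gene passed, and 15 of 16 had a positive fold change in involved ileum. The proteoglycan BGN was at 2.22 ± 0.79 (log2, SE, 3 of 5 involved libraries above the uninvolved median), tenascin TNC at 1.91 ± 0.65 (5 of 5), COL1A1 at 1.62 ± 0.58 (3 of 5), SPARC at 1.32 ± 0.43 (5 of 5) and COL1A2 at 1.15 ± 0.31 (5 of 5). None passed over all genes and 0 adjusted over the list alone, while camera called the list up (median 1.05, adjusted p = 2.5e-09, and adjusted p = 0.353 with an estimated correlation). The oxidative phosphorylation list was called down (median -0.17, adjusted p = 0.0105, and 0.353 as the adjusted p with an estimated correlation). Immunoglobulin transcripts moved against those of the fibroblast class, all 7 being lower over the list alone, with IGHA2 at -6.44 ± 1.41 (0 of 5, list median -6.06, adjusted p = 1.78e-05, and adjusted p = 0.353 with an estimated correlation). With 5 libraries in each group edgeR called 0 of 974 genes, 34 had an unadjusted p below 0.05 and DESeq2 called 3. V2 libraries were too few (4 against 4) to test.

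**Figure D3:**
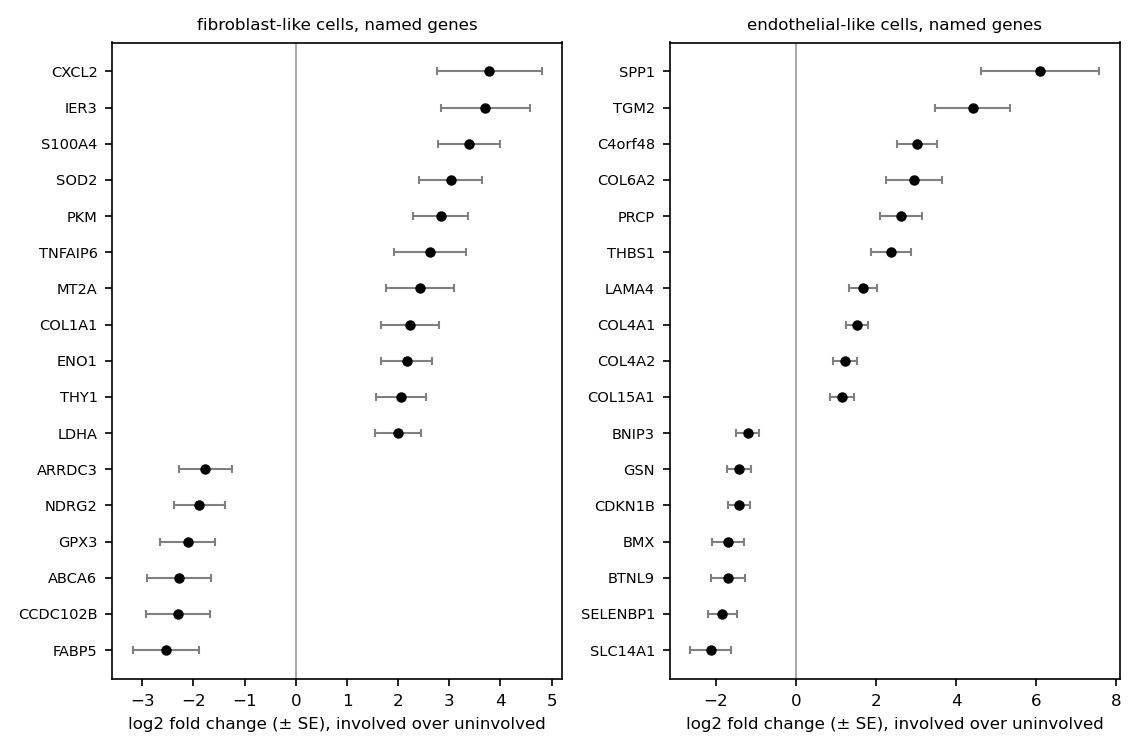
Log2 fold change, involved over uninvolved, with its SE (x axis) of the named genes (y axis, immunoglobulin left out) in fibroblast-like and endothelial-like cells. In fibroblast-like cells CXCL2 is at 3.78 and FABP5 at -2.54, and in endothelial-like cells SPP1 is at 6.10 and SLC14A1 at -2.12.

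In endothelial-like cells of involved ileum 4 of 10 matrix genes rose, and of 12 capillary genes 1 rose and 1 fell. The type IV collagen chains COL4A1 (ENSG00000187498) and COL4A2 (ENSG00000134871), the base of vessel basement membranes, rose by 1.53 ± 0.28 (log2, SE, adjusted p = 0.0120) and 1.23 ± 0.31 (adjusted p = 0.0444). The laminin LAMA4 (ENSG00000112769) rose by 1.67 ± 0.34 (adjusted p = 0.0131), and all 3 had 10 of 10 involved libraries above the uninvolved median. COL6A2 rose by 2.95 ± 0.70 (adjusted p = 0.0447, 8 of 10), COL15A1 by 1.15 ± 0.30 (adjusted p = 0.0457, 10 of 10) and thrombospondin THBS1 by 2.38 ± 0.51 (adjusted p = 0.0258, 9 of 10). The crosslinking enzyme TGM2 rose by 4.41 ± 0.93 (adjusted p = 0.0310, 7 of 10) and osteopontin SPP1 by 6.10 ± 1.48 (adjusted p = 0.0499, 9 of 10). C4orf48 (ENSG00000243449) rose by 3.03 ± 0.50 (adjusted p = 0.0120, 10 of 10) and the peptidase PRCP by 2.62 ± 0.52 (adjusted p = 0.0182, 9 of 10). Each fall left 0 of 10 libraries above the median. The urea transporter SLC14A1 fell by -2.12 ± 0.51 (adjusted p = 0.0444), SELENBP1 (ENSG00000143416) by -1.83 ± 0.36 (adjusted p = 0.0120) and the capillary gene BTNL9 by -1.69 ± 0.42 (adjusted p = 0.0444). The kinase BMX fell by -1.69 ± 0.40 (adjusted p = 0.0340), the cell cycle inhibitor CDKN1B by -1.42 ± 0.28 (adjusted p = 0.0126), gelsolin GSN by -1.41 ± 0.31 (adjusted p = 0.0246) and BNIP3 by -1.20 ± 0.28 (adjusted p = 0.0340).

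Of 10 matrix genes 4 rose in endothelial-like cells over all genes and 7 adjusted over the list alone (list median 1.24, adjusted p = 2.55e-05). None of the 7 list calls in this class held with an estimated correlation (adjusted p = 0.353 for the matrix and capillary lists, up to 0.468). The capillary list was called down (median -0.58, adjusted p = 0.00225), with 1 rise (COL15A1) and 1 fall (BTNL9) of 12 over all genes and 1 rise and 2 falls over the list alone, the fenestral protein PLVAP being at -0.71 ± 0.21 (1 of 10). Of 17 venular and activated endothelium genes 6 rose and 1 fell over the list alone and 0 passed over all genes. The leukocyte-capturing selectins SELE and SELP rose by 2.93 ± 0.85 (7 of 10) and 2.20 ± 0.63 (10 of 10), CSF3 by 2.97 ± 0.84 (8 of 10) and the venular receptor ACKR1 by 1.04 ± 0.35 (10 of 10), while OSMR fell by -0.92 ± 0.37 (2 of 10). Camera did not call the list (median 0.46, adjusted p = 0.0957). Stress genes (median -0.48, adjusted p = 0.000279), type I interferon genes (-0.61, adjusted p = 0.0271) and metallothioneins (-0.81, adjusted p = 0.0441) were called down, with JUN at -1.37 ± 0.39. Oxidative phosphorylation (0.24, adjusted p = 0.00666) and immunoglobulin transcripts (1.00, adjusted p = 0.00695) were called up, with IGHG1 at 4.15. The type I interferon call was also lost within V2 (adjusted p = 0.123), and the metallothionein (0.0657) and immunoglobulin (0.173) calls with ambient counts subtracted.

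In all, 80 of 4179 genes passed in endothelial-like cells, 59 up and 21 down, in 10 against 7 libraries, and within V2 libraries 39 passed, 34 of them shared. Of the 17 named genes 9 kept their call within V2 and 8 kept their direction with adjusted p from 0.0678 to 0.119. COL4A1, C4orf48 and SELENBP1 kept the call in each of 17 fits without 1 library, while COL6A2 kept it in 4, BTNL9 and COL15A1 in 5 and COL4A2 and SLC14A1 in 6 of 17, and SPP1 in 4 of 11. Requiring 1500 UMIs per cell gave 37 genes and keeping doublets 50. Without the uninvolved replicate in brackets the count was 10 (11), 17 (5, 9), 26 (3), 30 (8) and 49 (1). Without the involved one it was 21 (4), 23 (6), 24 (3), 32 (7), 44 (10) and 179 (11).

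In NK/ILC-like cells 0 of 6 and in B-like cells 1 of 7 interferon gamma response genes rose in involved ileum, adjusted over the list alone, and camera called both lists up. With an estimated correlation neither call held (adjusted p = 0.353 each), nor did the other 4 list calls in these classes (adjusted p from 0.353 to 0.581). In B-like cells the list had a median of 0.47 (camera adjusted p = 0.000399). GBP2, a guanylate-binding protein, rose by 1.69 ± 0.49 (log2, SE, 8 of 10 involved libraries above the uninvolved median), the 1 of 7 genes to pass when adjusted over the list alone, and 0 passed over all genes. The MHC class II list was also called up there (median 0.14, adjusted p = 0.0255), HLA-DOA being at 0.54 ± 0.17 (9 of 10). In NK/ILC-like cells the interferon gamma (median 0.35, adjusted p = 0.0264), NF-kB (0.14, adjusted p = 0.0371, NFKB1 at 0.63 ± 0.20, 9 of 11) and immunoglobulin (0.86, adjusted p = 6.96e-06, IGLC3 at 1.56 ± 0.54) lists were called up. The stress list was called down (-0.20, adjusted p = 0.0371). Of the NK/ILC-like cells 55.0% came from cluster 19 and 43.8% from cluster 16 in involved ileum, against 37.9% and 61.5% in uninvolved ileum. Within V2 the calls of MHC class II in B-like (adjusted p = 0.124) and of interferon gamma (0.0844) and NF-kB (0.151) in NK/ILC-like cells were lost, NF-kB also without the libraries rich in epithelial-like cells (0.173), and the stress call in NK/ILC-like cells was lost with ambient counts subtracted (0.0787). By edgeR 0 of 1652 genes passed in NK/ILC-like and 0 of 3589 in B-like cells, with 76 and 83 at an unadjusted p below 0.05 and 1 and 5 by DESeq2. In B-like cells 1 gene passed without uninvolved replicate 11, involved replicate 5 or involved replicate 9. The naive (median 0.37, adjusted p = 0.352) and memory (0.06, adjusted p = 0.989) B cell lists were not called.

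Across the classes camera called 47 of 93 lists between involved and uninvolved ileum, 29 up and 18 down, and 42 within V2 libraries, 38 of them shared. With an estimated correlation 0 held, and fry, which tests the direction of a list without comparing it with other genes, called 1, the residency list in T-like cells (adjusted p = 0.0310). None of the targets and receptors of Crohn therapies passed over all genes in the 8 classes tested, which held 15 such genes in T-like cells, 11 in MNP-like and 8 in endothelial-like cells. Adjusted over the list alone, TNF and IL1B rose in MNP-like cells. For 9 uncalled lists median and test differed in sign. These were stress in B-like cells (median 0.04, tested down, adjusted p = 0.184) and in pericyte and smooth muscle-like cells (0.01, down), memory B cell in B-like (0.06, down), metallothionein in plasma-like (0.06, down), epithelial markers in endothelial-like (0.01, down), immunoglobulin in MNP-like (-0.41, up), Th17 in T-like (-0.18, up) and therapy targets in MNP-like (-0.05, up) and T-like cells (-0.04, up). The uncalled cytotoxic list in T-like cells had a median of -0.21 and a mean of 0.06. In the Th17 list CTSH and IL1R1 rose by 1.25 ± 0.32 and 0.88 ± 0.28 over the list alone.

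**Figure D4:**
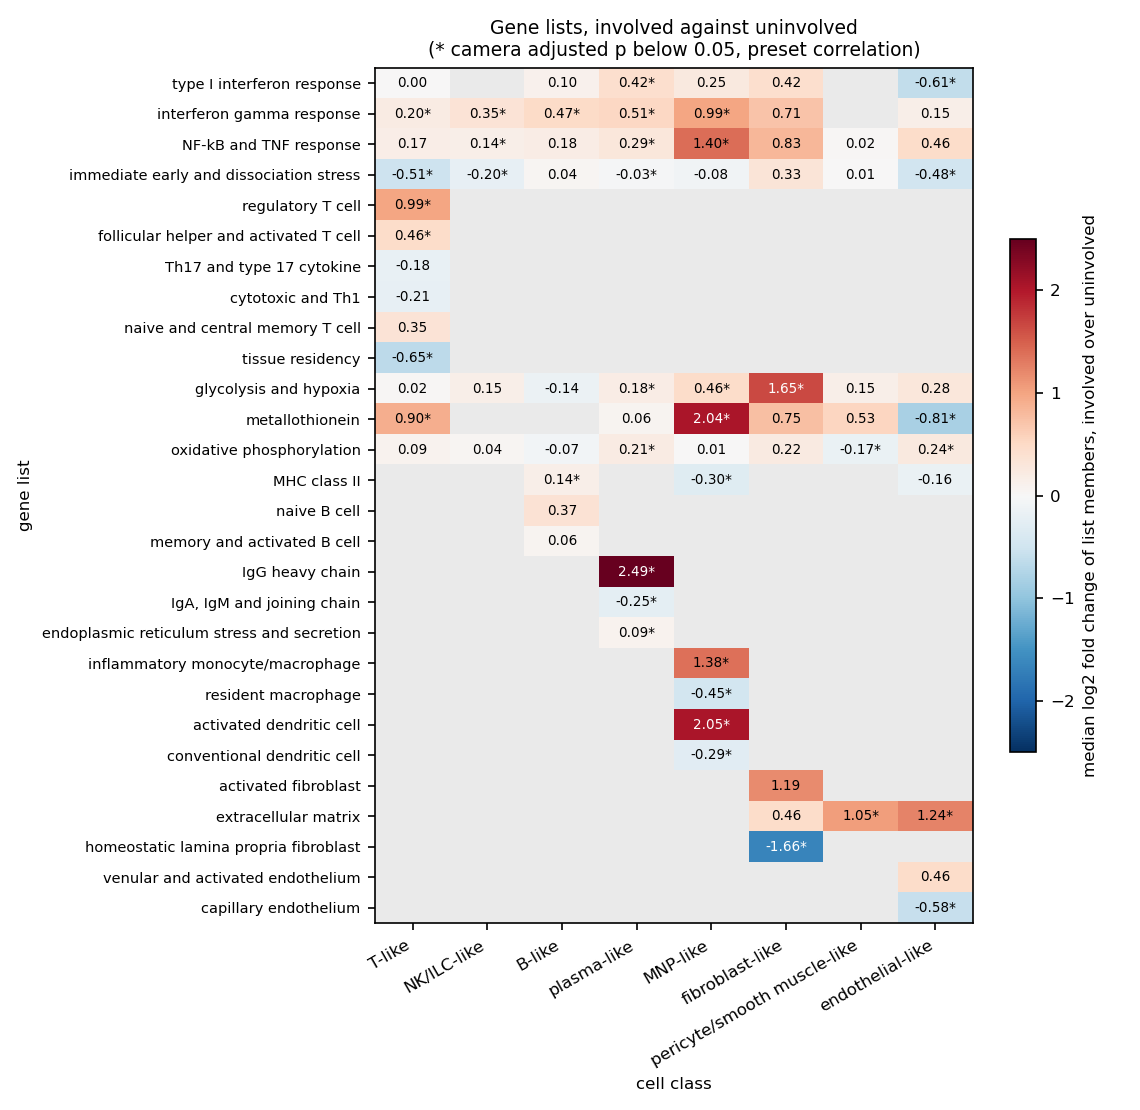
Median log2 fold change, involved over uninvolved, of the tested members of each gene list (y axis) in each class (x axis), with camera calls at an adjusted p below 0.05 starred and untested pairs in grey. In MNP-like cells the activated dendritic cell list is at 2.05 and the inflammatory list at 1.38, and in fibroblast-like cells the homeostatic list is at -1.66.

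The next comparison asks whether cell states vary together across involved libraries. The follicular helper and activated T cell list rose with the regulatory T cell list in T-like cells, and the IgG percent of plasma-like cells was higher where the follicular helper list was higher. The former pair had Pearson r = 0.921 over 11 libraries (permutation p = 4e-05, adjusted p = 0.00084 over 21 pairs) and Spearman rho = 0.891 (p = 0.00049, adjusted p = 0.0103), and r = 0.856 (permutation p = 0.00259) without the 2 farthest libraries. It was 0.940 within V2. Both lists were measured in the same T-like cells. Genes of both (CXCL13, CTLA4 and TIGIT) lead cluster 8, and its share was not separated from the list levels. In uninvolved libraries r of this pair was 0.837, which also passed. It fell to 0.641 (permutation p = 0.0806) without the 2 farthest, and rho was 0.573 (adjusted p = 0.379). For IgG and follicular helper genes r was 0.783 (permutation p = 0.00586, adjusted p = 0.0615), which did not pass, and rho 0.827 (p = 0.00285, adjusted p = 0.0299), which did. The r was 0.753 (p = 0.0194) without the 2 farthest libraries and 0.711 (p = 0.0208) within V2. In uninvolved libraries r was 0.535 (p = 0.0888). The IgG percents of involved libraries left a gap between 26.99% and 54.15%, with 4 libraries above it, too few to test within.

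All 21 pairs of states had a positive r, with a median of 0.57, and 8 had an unadjusted p below 0.05. The inflammatory MNP list and the activated fibroblast list had r = 0.838 over 8 libraries (exact permutation p = 0.0099, adjusted p = 0.0693) and rho = 0.738, and r = 0.748 (exact permutation p = 0.0889) without the 2 farthest libraries. In all 1 pair passed by r, and 3 passed without involved replicate 1 or 10, 6 without involved replicate 2 and 2 without involved replicate 4 or 7. Within V2 libraries 3 pairs passed.

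**Figure D5:**
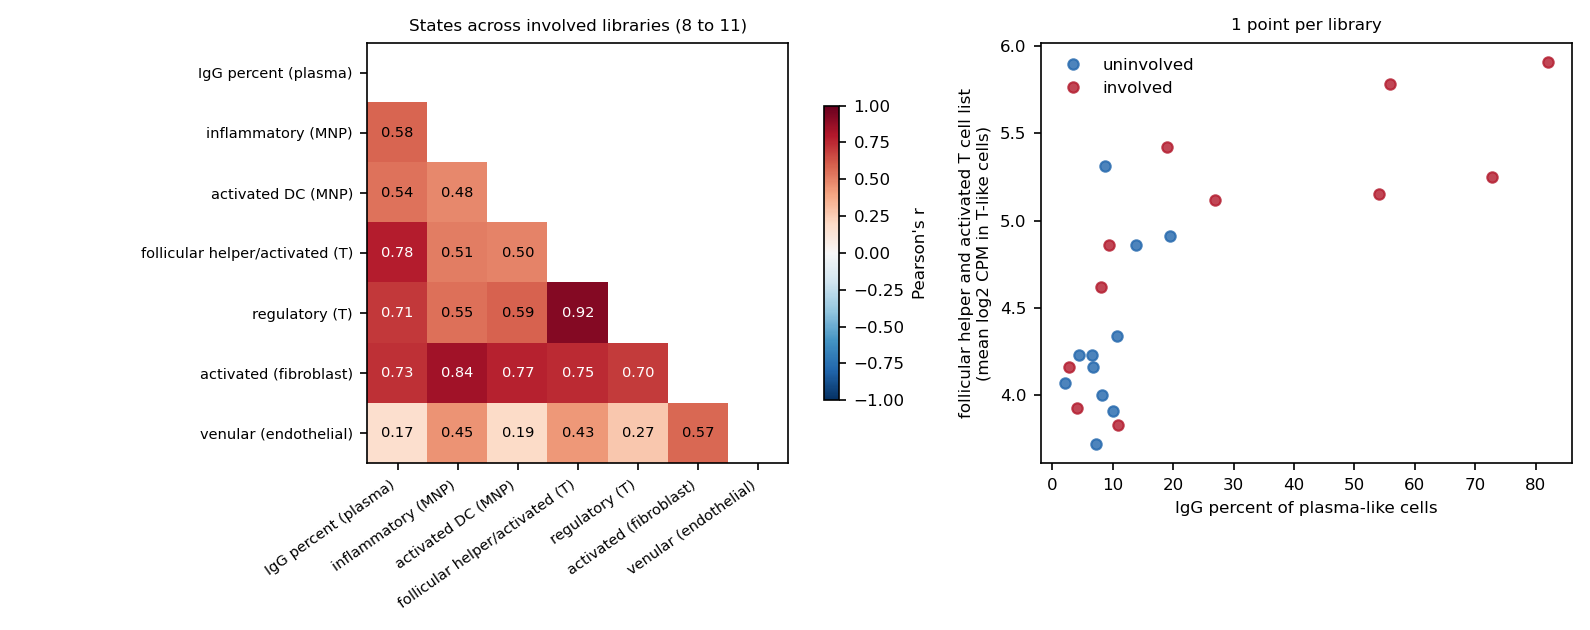
Left, Pearson r (colour) between cell states (both axes) across involved libraries, 8 to 11 per pair, all 21 positive, with r = 0.921 for the follicular helper and regulatory T cell lists. Right, mean log2 CPM of the follicular helper and activated T cell list (y axis) against the IgG percent of plasma-like cells (x axis), 1 point per library, with r = 0.783 in involved ileum and 0.535 in uninvolved ileum.

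The comparison of blood with uninvolved ileum asks how circulating cells of a class differ from those of the tissue. The labels give blood the same digestion as tissue, and whether blood was digested is not known, which limits the stress results here. Cluster 5, with the cytotoxic genes GNLY, NKG7, GZMH and FGFBP2, made up 26.3% ± 10.9 (SD, n = 9) of blood cells and 0.194% ± 0.195 (n = 11) of uninvolved cells. Plasmacytoid dendritic cells were at 0.523% ± 0.244 against 0.0547% ± 0.116 and MNP-like cells at 12.8% ± 7.82 against 5.23% ± 2.17. Plasma-like cells were at 0.409% ± 0.289 against 20% ± 21.6 and cluster 13 at 0.123% ± 0.181 against 3.43% ± 2.36.

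By the exact permutation test adjusted over the classes, cluster 5 (adjusted p = 5.4e-05, higher in 9 of 9 blood libraries, within V2 25.1 points) rose. Plasmacytoid dendritic cells (adjusted p = 0.000125, 9 of 9, within V2 0.401 points) and MNP-like cells (adjusted p = 0.0102, 7 of 9, within V2 7.47 points) rose too. Cluster 13 (adjusted p = 0.000125, 0 of 9 above, within V2 -3.57 points) and plasma-like cells (adjusted p = 0.000991, 0 of 9, within V2 -13.7 points) fell. Mast-like cells were at 0.176% ± 0.150 against 0.569% ± 0.507 (adjusted p = 0.0491, 1 of 9 above). That call was lost within V2 (-0.411 points, adjusted p = 0.0628) and without blood replicate 1, 2, 4, 5, 6, 7, 8 or 9 or uninvolved replicate 1, 2, 3, 5, 6, 9 or 11 (-0.291 to -0.412 points, adjusted p from 0.0514 to 0.0885). T-like cells (39.5% ± 11.8 against 52.1% ± 16.1, adjusted p = 0.0839) did not pass, but did within V2 (-16.0 points, adjusted p = 0.00765), without uninvolved replicate 1 (-16.9 points, adjusted p = 0.00407) and without blood replicate 4 (-15.0 points, adjusted p = 0.0499). B-like cells (12.8% ± 5.96 against 8.90% ± 10.4, adjusted p = 0.353) passed without uninvolved replicate 4 (6.75 points, adjusted p = 0.0160). NK/ILC-like cells, without cluster 5, were at 7.24% ± 4.76 against 4.65% ± 2.94 (adjusted p = 0.172). They passed in other clusterings that counted a cluster led by GZMH, FGFBP2 and GNLY among them.

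Circulating T-like cells had lower residency, Th17 and immediate early genes and higher naive genes than those of uninvolved ileum. They lay in other clusters, 88.6% in cluster 1 and 9.8% in cluster 18, against 49.0% in cluster 0 and 32.3% in cluster 3. All 10 residency genes fell, both over all genes and adjusted over the list alone, with RGS1, a brake on chemokine signals, at -8.96 ± 0.60 (log2, SE). The cytokines IL22, which was not counted in blood (at least 661-fold lower, against a floor of 3 counts over the group), and IL17A (-9.13 ± 0.73) fell with the chemokines CCL20 (-7.64 ± 0.53) and CCL4 (-8.17 ± 0.73). The stress gene ATF3 had 3 counts in blood against 5936, a 2570-fold lower level (95% counting interval 880 to 12500). CCR7, the chemokine receptor for entry into lymph nodes, rose by 2.64 ± 0.51, S1PR4 by 2.69 ± 0.18, ITGB1 by 2.56 ± 0.22, TRABD2A by 2.57 ± 0.25 and NGFRAP1 by 2.87 ± 0.31. CCL4L2 (-8.73 ± 0.86) and CCL3L3 (-8.20 ± 0.84) fell too, though they share sequence with CCL4 and CCL3. Each rise was seen in 9 of 9 blood libraries and each fall left 0 of 9 above the uninvolved median, and the adjusted p of CCR7, 0.000281, was the highest among these genes.

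Among the list calls in blood T-like cells those of the residency, stress, follicular helper (adjusted p = 0.0084 each with an estimated correlation), Th17 and NF-kB (0.0157 each) lists held with an estimated correlation. Those of the naive and cytotoxic (adjusted p = 0.0561 each with an estimated correlation) and regulatory (0.107) lists did not. Over all genes tested, 10 naive genes rose and 1 fell of 12 in T-like cells (median 2.07, adjusted p = 3.46e-06). Falls were seen in 7 of 9 Th17 genes (median -2.97, adjusted p = 1.64e-08), 10 of 11 follicular helper and activated genes (-1.86, adjusted p = 4.88e-07), 10 of 11 regulatory genes (-1.46, adjusted p = 3.69e-05) and 11 of 18 cytotoxic genes (-1.40, adjusted p = 3.29e-06). So they were in 11 of 14 NF-kB genes (-1.81, adjusted p = 4.87e-09), 16 of 18 stress genes (-3.60, adjusted p = 1.76e-16) and all 10 residency genes (-4.91, adjusted p = 8.89e-12). Adjusted over the list alone these counts differed for cytotoxic genes (12 fell and 1 rose) and NF-kB genes (12 fell). The cytotoxic list turned to a rise without a call when clusters 5 and 13 were counted as T-like (adjusted p = 0.114). Of 15 therapy targets and receptors 10 passed over all genes, with S1PR1, the receptor that lets lymphocytes leave tissue, up by 3.46 ± 0.30, IL23R at -3.48 ± 0.32, IL12RB2 at -3.52 ± 0.34 and TNF at -3.56 ± 0.41. Epithelial transcripts were lower in blood too, and free RNA could account for up to 100% of those named here, while remaining doublets were not tested as a source. PHGR1 had 2 counts against 1398 (909-fold lower, 251 to 7520), FABP1 1 against 641 (834-fold, 149 to 33000), TFF3 1 against 464 (604-fold, 108 to 23900) and OLFM4 was at least 173-fold lower. S100A9 (6.95 ± 0.63) was higher in blood T-like cells, where free RNA could account for 100% of it. By edgeR 4056 of 8834 genes passed, 2014 up and 2042 down, and 4476 within V2 libraries, where each of the 30 genes that the naming rule picks kept its call.

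Circulating B-like cells had higher naive genes and lower immediate early genes. Of these cells 97.7% lay in cluster 4, against 38.7% of uninvolved ones, of which 61.3% lay in cluster 7. TCL1A, a marker of naive B cells, rose by 3.0 ± 0.57 (log2, SE), the interleukin 4 receptor IL4R by 2.48 ± 0.43 (8 of 9 blood libraries above the uninvolved median), PPP1R14A by 4.05 ± 0.44 and the surface receptor CD180 by 2.78 ± 0.28. RGS1 was lower by 8.71 ± 0.51 (log2 fold change -8.71) and the transcription factors NR4A2 and NR4A1 changed by -6.80 ± 0.48 and -5.32 ± 0.39. The growth factor AREG changed by -6.38 ± 0.42, SOCS3 by -6.00 ± 0.39 and CD83 by -4.21 ± 0.22, and each of these had 0 of 9 above. The adjusted p of these genes was at most 0.000546 (TCL1A). Of the list calls in blood B-like cells that of stress held with an estimated correlation (adjusted p = 0.0084), and the others did not (adjusted p = 0.123 for naive, 0.108 for memory, 0.227 for type I interferon and 0.228 for glycolysis). Over all genes 8 of 10 naive genes rose and 1 fell (median 1.14, adjusted p = 5.62e-05), and 13 of 17 stress genes fell (-1.98, adjusted p = 3.41e-13). Of memory genes 3 of 8 fell and 1 rose (-0.63, adjusted p = 0.0110), 4 of 7 type I interferon genes rose (0.85, adjusted p = 0.0422, lost within V2 at 0.0805) and 3 of 8 glycolysis genes fell (-0.21, adjusted p = 0.0214). Adjusted over the list alone these counts differed for stress genes (15 fell) and memory genes (3 fell and 2 rose). The heat shock genes HSPA1B (-5.63 ± 0.45) and HSPA1A are near identical, so their separate counts are uncertain. By edgeR 1323 of 4213 genes passed, 641 up and 682 down, and 1445 within V2 libraries.

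Circulating MNP-like cells had lower resident macrophage and MHC class II genes. They lay in other clusters, 75.2% in cluster 10 and 18.8% in cluster 20, against 87.2% in cluster 11 and 8.1% in cluster 24. The alarmins S100A8 and S100A12 and the proteoglycan VCAN, all abundant in blood monocytes, rose by 6.51 ± 0.72, 6.13 ± 0.64 and 5.03 ± 0.49 (log2, SE), CDA by 5.68 ± 0.39 and NRGN, which is also a leading gene of the platelet-like cluster, by 5.09 ± 0.34, each in 9 of 9 blood libraries. The selenium carrier SEPP1 (ENSG00000250722) had 1 count in blood against 6321 (13200-fold lower, 95% counting interval 2370 to 523000), IGF1 was at least 339-fold lower, and CCL20 had 1 count against 786 (1650-fold lower, 295 to 65100). The complement gene C1QC changed by -7.47 ± 0.62, the lipid carrier APOE by -8.56 ± 0.87, DNASE1L3 by -6.59 ± 0.61, RGS1 by -9.82 ± 0.34 and AREG by -9.71 ± 0.44, each with 0 of 9 above. The chemokine genes CXCL2 and CXCL3 changed by -7.42 ± 0.68 and -7.59 ± 0.72, and immunoglobulin transcripts were lower too (IGHA2 -7.55, adjusted p = 0.000787, the highest among these genes, with free RNA up to 29.5% among the 4 named).

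The resident macrophage (adjusted p = 0.000522) and MHC class II (0.0391) calls held with an estimated correlation, and those of the stress and activated dendritic cell (adjusted p = 0.0561 each), conventional dendritic cell (0.0920), NF-kB (0.180) and type I interferon (0.245) lists did not. Over all genes, 16 of 17 resident macrophage genes fell in MNP-like cells and 1 rose (median -4.76, adjusted p = 1.43e-15), and all 11 MHC class II genes fell (-1.87, adjusted p = 1.71e-09). Of the dendritic cell lists 9 of 11 conventional dendritic cell genes (-1.97, adjusted p = 9.89e-06) and 5 of 7 activated dendritic cell genes fell (-2.23, adjusted p = 0.000641), and 15 of 18 stress genes fell and 1 rose (-1.90, adjusted p = 5.67e-09). NF-kB genes fell in 10 of 15 cases and rose in 2 (-0.93, adjusted p = 0.000395), and 8 of 12 type I interferon genes rose (0.89, adjusted p = 0.00303). Adjusted over the list alone these counts differed for activated dendritic cell genes (6 fell) and type I interferon genes (10 rose). The inflammatory list, which holds both monocyte genes and cytokines, had 6 rises and 11 falls of 19 and was not called (median -2.43, adjusted p = 0.0565). Therapy targets passed in 7 of 10 cases, with IL1B at -4.42 ± 0.35, TNF at -2.43 ± 0.42 and TNFRSF1B at 1.36. By edgeR 2199 of 5659 genes passed, 987 up and 1212 down, and 2463 within V2 libraries. Over the 3 classes camera called 23 of 39 lists in blood, 4 up and 19 down, and 8 with an estimated correlation.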

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

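Tests of free RNA for inflammatory MNP-like genes, of depth per cell and of other pericyte and smooth muscle-like splits were written before their results were seen, and the others here after. In groups of 4 to 10 libraries the sample at each end was compared with its nearest neighbour by Dixon's test, which chance passes in about 1 in 20 groups. Of 19 groups 3 passed, each in blood. Cluster 13 made up 0.563% of cells in blood replicate 1, against 0 to 0.209% in the others (gap over range 0.629, critical value 0.493). Immunoglobulin transcripts made up 5.39% of free RNA in blood replicate 1, against 0.13% to 2.66% (0.519). Erythroid-like cells made up 24.2% of all cells in blood replicate 3, against 0 to 2.75% (0.886).

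The change of a list between involved and uninvolved ileum was also compared between each class and T-like cells of the same libraries, by permutation with adjustment over 44 tests, of which 16 had an unadjusted p below 0.05 and 10 passed. The change of the stress list in T-like cells lay below that in NK/ILC-like (difference 0.40 on the log2 scale, adjusted p = 0.0450), B-like (0.51, adjusted p = 0.0436), plasma-like (0.36, adjusted p = 0.0436) and MNP-like cells (0.44, adjusted p = 0.0450), and in fibroblast-like cells they differed by 1.13 (0.46 against -0.67, adjusted p = 0.0436). The glycolysis list differed by 1.19 in fibroblast-like cells (1.37 against 0.18, adjusted p = 0.0436) and by 0.34 in MNP-like cells (0.36 against 0.03, adjusted p = 0.0436). NF-kB genes differed by 0.94 in MNP-like cells (0.97 against 0.03, adjusted p = 0.0496). Metallothioneins differed by -2.11 in endothelial-like cells (-0.80 against 1.31, adjusted p = 0.0436) and oxidative phosphorylation genes by 0.21 (0.26 against 0.05, adjusted p = 0.0496).

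The IgG percent of plasma-like cells was higher in involved ileum. Free immunoglobulin RNA made up 14.3% ± 8.28 of free RNA in involved and 7.96% ± 8.59 in uninvolved ileum (permutation p = 0.0954). As the cause of the calls it would need IgG cells to carry about the UMIs that free RNA supplies, and in the involved library with the lowest median they carried 137 times as many. Within V2 libraries the difference was 16.8 points (permutation p = 0.0571). Each group held 1 V1 library, so an uneven share of V1 libraries was not its source. Whether V1 chemistry enlarged the difference cannot be told with 1 V1 library per group. Inflammation, the difference the design names, stays open and untested as a cause.

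The inflammatory list was higher in MNP-like cells of involved ileum. If digestion had caused this, the stress genes would rise by a like amount, and their median was -0.08. Resampling these genes gave a spread of 0.07, which measures variation between genes and not between libraries. If free RNA had caused it, it would need to supply most counts of the 16 members that rose, and it could account for at most 3.4% (CCL4, median 0.7%). A change in which cells make up the class, such as the cells of cluster 22, or a change within cells may both contribute, and these data do not separate them.

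The follicular helper and activated T cell list was higher where the IgG percent was higher. The partial correlation given median UMIs per cell was 0.728 (permutation p = 0.0129), r with ambient counts subtracted 0.774 (permutation p = 0.00693) and r within V2 libraries 0.711 (permutation p = 0.0208), so depth, free RNA and chemistry do not account for it as a whole. The relation was not past its threshold by r over 21 pairs, and a shared difference between samples in follicular tissue is a candidate explanation that was not tested.

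Other splits of the same libraries into groups of the same sizes, 100 per count with the real one included (99 for pericyte and smooth muscle-like cells), show how often another grouping calls as many. As many genes were called by 1 split, the real one, in fibroblast-like cells (112, highest other 6), endothelial-like cells (80, highest other 78) and blood T-like (4056, highest other 1302), B-like (1323, highest other 1) and MNP-like cells (2199, highest other 262). With 100 splits this makes chance an unlikely source of these counts but does not exclude it. In endothelial-like cells another split came close to the real count. In T-like cells 4 of 100 splits, the real one among them, called as many as the real 5, and the highest other called 435. The count of 5 thus does not exclude chance, and what the split with 435 separates was not examined. Where the real count was 0 every split is as large by construction, so nothing follows about chance: NK/ILC-like (100 splits, highest other 2), B-like (100, highest other 3), plasma-like (100, highest other 145), MNP-like (100, highest other 18) and pericyte and smooth muscle-like cells (99, highest other 5). What the splits with 145 and 18 separate was not examined either. For the count of called lists the real grouping ranked first in involved ileum, with another split close to it (1 split as large, real 47, highest other 43), and not in blood (6 as large, real 23, highest other 26). The median of the other splits was 20 lists in involved ileum and 8 in blood, so a single list call at the preset correlation does not by itself exclude chance.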

How the results depend on the processing

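No paired analysis was possible because the labels name no patient for an ileal library. Fits without replicate 2 of each ileal group (the libraries rich in epithelial-like cells), with clusters from another random seed or with other clusters counted were chosen after seeing the data, and the other settings before. Where a setting changed a result, the cause was not tested unless fewer libraries, cells or genes enter by its construction. The small classes were limited even in simulated counts, where planted 2-fold changes were called for 37% of genes in fibroblast-like and 12% in pericyte and smooth muscle-like cells. These rates leave out structure among libraries and need not hold in the real counts. Under settings other than leaving out 1 library 188 share values kept direction and call, 6 reversed, 6 lost and 3 gained a call, and on leaving out 1 library these counts were 457, 13, 15 and 3. For gene counts 85 stayed within 1.5 times, 21 rose and 11 fell beyond it, and for single named genes 240 kept their call, 100 lost it and 1 reversed in involved ileum, against 835 and 2 in blood, where none reversed. Leaving out 1 library kept the call of named genes in 264 cases and lost it in 303 in involved ileum, and kept it in 1489 and lost it in 7 in blood.

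In involved ileum the uncalled cluster 13 share difference reversed to -0.659 points with at least 1500 UMIs per cell and to -0.388 within V2, the mast-like one to -0.0549 in log2 percents and -0.131 without the libraries rich in epithelial-like cells, and the lymphatic one to 0.0215 with at most 10% mitochondrial UMIs. Leaving out 1 library gave -0.187 to 1.17 for cluster 13, -0.233 to 0.217 for mast-like, -0.330 to 0.0224 for pericyte and smooth muscle-like, -0.367 to 0.706 for endothelial-like and -0.171 to 0.0534 points for lymphatic cells. In blood the T-like difference passed within V2 (-16.0 points), and so did that of NK/ILC-like cells at the higher Leiden resolution (16.1) and with another random seed (19.4). The MNP-like call was lost with at least 1500 UMIs (8.11 points). That of mast-like cells was lost or reversed with at least 1500 UMIs (0.315), at most 10% mitochondrial UMIs (-0.274), all cells in the denominator (-0.265), log2 percents (-1.27), V2 alone (-0.411) and without the libraries rich in epithelial-like cells (-0.291). Leaving out 1 library gave -16.9 to -10.5 points for blood T-like, 2.65 to 6.75 for B-like and -0.446 to -0.291 for mast-like cells. The IgG difference within V2 was 16.8 points.

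In involved ileum the gene count in T-like cells went from 5 to 8 with RLE, 70 with DESeq2, 0 with at least 1500 UMIs, 9 with chemistry as a covariate and 2 within V2, without the libraries rich in epithelial-like cells and with another random seed. In fibroblast-like cells 112 became 262 with DESeq2, 416 with no filter, 0 with at least 1500 UMIs, 16 with chemistry as a covariate, 7 within V2 and 63 with another random seed. In endothelial-like cells 80 became 152 with DESeq2, 405 with no filter, 37 with at least 1500 UMIs, 50 with doublets kept and 39 within V2. Where edgeR called 0, DESeq2 called 1 in NK/ILC-like, 5 in B-like, 18 in plasma-like, 136 in MNP-like and 3 in pericyte and smooth muscle-like cells. With no filter 8 were called in NK/ILC-like, 22 in B-like, 2 in MNP-like and 22 in pericyte and smooth muscle-like cells, where subtracting ambient counts gave 1. Blood counts with no filter were 2291 in B-like and 4517 in MNP-like cells. On leaving out 1 library the counts ranged from 0 to 67 in T-like, 0 to 1 in B-like, 0 to 4 in plasma-like, 0 to 82 in MNP-like, 0 to 352 in fibroblast-like and 10 to 179 in endothelial-like cells. IGLC2 in fibroblast-like cells turned to -1.87 with doublets kept.

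Of the 47 lists called in involved ileum 0 held with an estimated correlation and 1 by fry, and of the 23 in blood 8 held with an estimated correlation. The immunoglobulin list in T-like cells reversed with ambient counts subtracted, a step scaled to remove it (adjusted p = 0.460). The cytotoxic list in blood reversed when clusters 5 and 13 were counted as T-like (adjusted p = 0.114). Passing correlations went from 1 to 3 within V2, 6 with at least 50 cells per library (of 15 pairs tested, against 21 otherwise), 2 in uninvolved libraries (17 of 21 pairs positive) and 6 without the libraries rich in epithelial-like cells, and on leaving out 1 library they ranged from 1 to 6. In uninvolved libraries 1 passing pair was negative, the regulatory T cell and venular endothelium lists (r = -0.95 over 7 libraries, exact permutation p = 0.00278, adjusted p = 0.0318, rho = -0.821, against r = 0.268 in involved ileum, and -0.736 with p = 0.15 without the 2 farthest). Also negative were the r of the activated dendritic cell and activated fibroblast lists (-0.09) and of the venular list with the inflammatory (-0.344) and follicular helper (-0.167) lists.

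Some settings had too few libraries. These were mast-like cells (3 against 4 libraries), fibroblast-like cells with at least 50 cells (5 against 2) or without cluster 30 (3 against 7), and pericyte and smooth muscle-like cells with at least 50 cells (1 against 2), at least 1500 UMIs (3 against 3), V2 alone (4 against 4), another random seed (2 against 3) or any one library left out. Leaving out the libraries rich in epithelial-like cells removed none from the fits of B-like, fibroblast-like, pericyte and smooth muscle-like and endothelial-like cells.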

Other observations

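In epithelial-like cells that remained after stripping 5 genes rose in involved ileum, and camera called both interferon response lists up although 0 of their members passed over all genes and neither call held with an estimated correlation (adjusted p = 0.233 each). The tests in this part were chosen after the data were seen, since the protocol removes most epithelium. BST2, the interferon-induced protein tetherin, was higher by 2.37 ± 0.34 (log2, SE, adjusted p = 0.00570), the surface protein TM4SF1 by 2.31 ± 0.37 (adjusted p = 0.00902), the metalloproteinase inhibitor TIMP1 by 2.16 ± 0.38 and PHLDA1 by 1.6 ± 0.30 (both adjusted p = 0.0246), each in 8 of 8 involved libraries above the uninvolved median. CAPN8, a calpain of the digestive epithelium, rose by 2.14 ± 0.36 (adjusted p = 0.00902) and was chosen after its values were seen. Of 10 interferon gamma genes 3 rose when adjusted over the list alone, among them WARS by 1.71 ± 0.38 and TAP1 by 0.77 ± 0.24, and camera called the list up (median 0.43, adjusted p = 0.00178). The type I interferon list was called up too (0 of 12 genes over the list alone, median 0.58, adjusted p = 0.00178). Stress genes (median -0.31, adjusted p = 0.00301, JUN by -0.58 ± 0.16 over the list alone), metallothioneins (-0.65, adjusted p = 0.0163) and oxidative phosphorylation genes (-0.20, adjusted p = 0.0149) were called down. The NF-kB (0.16, adjusted p = 0.0865) and glycolysis (0.03, adjusted p = 0.201) lists were not called, and the down calls were lost with an estimated correlation too (adjusted p = 0.233 for stress and adjusted p = 0.395 for the others).

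The class held 1463 cells in 8 involved and 3127 in 10 uninvolved libraries, and its share of all cells averaged 7.23% ± 15.0 against 13.7% ± 23.2 (permutation p = 0.498). By edgeR 5 of 7763 genes passed, 5 up and 0 down, 664 had an unadjusted p below 0.05 and DESeq2 called 60, and 6 passed within V2 libraries and 12 without the libraries rich in epithelial-like cells. Of 100 splits of the libraries 2 called as many as the real 5, and the highest other called 11, so the count does not exclude chance. Without the involved replicate in brackets the count was 2 (10), 3 (3, 7, 9), 8 (6) and 21 (2). Without the uninvolved one it was 3 (3, 4, 7, 9), 9 (2), 11 (6) and 28 (10).

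Free RNA and its share of cell counts were compared across groups. Free RNA could account for 4.13% ± 2.40 of the UMIs of involved cells, 4.49% ± 2.67 of uninvolved (permutation p = 0.741) and 2.77% ± 1.78 of blood cells. Immunoglobulin transcripts made up 0.489% ± 0.218, 0.357% ± 0.506 and 0.0208% ± 0.0246 of the UMIs of T-like cells in that order.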
